A study of Homo sapiens with 6 samples.

How the data were processed

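RNA-seq was carried out on total RNA of HCCLM3, a human hepatocellular carcinoma cell line, after 24 h with 10 µM ginkgolic acid or with the vehicle DMSO. Each group had 3 libraries, and the group and replicate number of each library were taken from the sample titles. The labels name TRIzol extraction and a commercial RNA-seq library kit, and whether the kit and the counting kept strand information is not given in the sources used here. The labels do not say whether replicates came from separate cultures, so p-values measure only the spread between these libraries, which may be technical.

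Per the submitters' processing notes, the authors used CASAVA 1.8, fastp, HISAT2 2.0.5, featureCounts 1.5.0-p3 and DESeq2 1.20.0 with the human genome build hg38, and the settings of each tool are not given in the sources used here. The authors deposited a comparison table of 403 genes with, per the file headers, values per library, the means of each group, a log2 fold change, a p-value, an adjusted p-value and the position of each gene. The deposited per-library values are a signal with no stated unit. In each library every value was a whole multiple of a single step, within a tolerance of 1e-06, as read counts divided by a library size factor would be. They are called normalised read counts here. The values of 1 read gave size factors between 0.921 and 1.139. A further deposited table is headed FPKM, but its 403 genes had the same order as the comparison table and its values differed by at most 4.6e-08, so its columns hold the same normalised read counts and no FPKM.

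Each of the 403 genes had an adjusted p-value under 0.05 and an absolute log2 fold change above 1 in the authors' deposited table. The values therefore hold genes already chosen on these libraries, and genes outside this selection were not analysed here. The sum of reads per library over the table's genes lay between 67006 and 98627. The total depth of each library is unknown. All 403 gene identifiers, positions and strands were equal to those of GENCODE release 29 (GRCh38), so coordinates are those of the deposited table on that build.

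The planned test for FPKM was kept for the normalised read counts, since the file named for FPKM held no FPKM. No count model was fitted here. Values were taken as log2(normalised read count + 1), and ginkgolic acid and DMSO libraries were compared with limma 3.58.1 in R 4.3.3, with an intensity trend in the variance prior. Genes needed a mean of at least 1 over the 6 libraries, which removed 0 genes. P-values were adjusted by Benjamini-Hochberg over the 403 genes, and the threshold was 0.05. Because the genes had been selected on the same libraries, these adjusted p-values describe the selected genes and are not independent evidence. Fold changes on this scale understate the change of genes with low counts. With 3 against 3 libraries an exact permutation test of a single gene cannot go below p = 0.1 (two-sided), so none was run. The fit was tested on simulated data for the 403 genes, with 200 genes changed and a dispersion of 0.01. In that simulation of ginkgolic acid against DMSO, 53.7% of genes changed 1.5-fold, 83.6% of those changed 2-fold and 100% of those changed 4-fold were called, and 2% of the unchanged genes.

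The choice of 29 gene lists with 650 distinct symbols, of the design, of the alternatives and of the rule for named genes was made before the data were examined. Of those symbols 639 matched a gene identifier. Members of the lists were counted by direction. Competitive list tests were not run, since the genes that a list would be compared with were not analysed here, and self-contained list tests were not run, since the members held had been selected for their difference on the same libraries. The rule named GPX4, HSPA8 and LAMP2, the 8 largest rises and the 8 largest falls past the threshold with no overlap between the groups, and up to 4 members of each list with the largest change. It gave 33 genes with values, some of which are not reported here.

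Libraries were compared by Pearson correlation across genes and by a chi-square test of recovered reads. The replicate numbers shared by the groups were checked by correlating the deviations of libraries from their group means. Alternatives changed the pseudocount, the filter, the scaling, the variance prior, the replicate block, the fold threshold and the set of libraries. Further steps used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.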

Results

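The response of HCCLM3 hepatocellular carcinoma cells to ginkgolic acid, an alkylated salicylic acid from Ginkgo biloba, was measured by RNA-seq. Cells were given 10 µM ginkgolic acid or DMSO for 24 h, with 3 libraries per group. The tables hold 403 genes that passed the authors' thresholds. On these genes the DMSO libraries had 67006, 72064 and 67572 reads and the ginkgolic acid libraries 79066, 82297 and 98627 reads. Across these genes, log2 values of libraries of the same group correlated at r = 0.961 to 0.971 and those of different groups at r = 0.726 to 0.784. Genes are not independent replicates, and the gap between these ranges follows in part from the choice of genes that differ. No pair of libraries agreed within sampling noise in a chi-square test of reads, so none looked like a repeat sequencing run of another library. This does not show that the libraries came from separate cultures. All 6 were kept as separate samples.

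The series title asks about HSPA8, the cytosolic chaperone of chaperone-mediated autophagy, and GPX4, the lipid hydroperoxide reductase that restrains ferroptosis. GPX4, HSPA8 and LAMP2, which encodes the lysosomal receptor of that pathway, were not analysed here, since the comparison covers the 403 selected genes. None of the 22 genes of the ferroptosis defence list, the 24 of the ferroptosis execution list or the 18 of the chaperone-mediated autophagy list was among them. This count does not show that they were unchanged, because a gene needed a change of more than 1 on the log2 scale to be selected.

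With ginkgolic acid the 4 selected members of the fatty acid oxidation list were higher than with DMSO. So were the 2 of the xenobiotic list and the 2 of the ATF4 list. The 2 selected members of the cell cycle list and the 2 of the immediate early list were lower. So few selected genes do not show a direction for a whole list. KRT17 and FGF21 were among the largest rises and CASC19 and TNS4 among the largest falls. Of the 403 genes in the authors' deposited table, 253 were higher with ginkgolic acid and 150 were lower. That is 62.8% higher, with an exact 95% binomial interval of 57.9% to 67.5%, which treats genes as independent. The median log2 fold change in the authors' deposited table was 1.34 for the higher genes and -1.30 for the lower genes, and 21 rose and 10 fell by at least 2 on that scale. The limma fit called the same 253 genes higher and 150 lower at an adjusted p under 0.05, where the highest adjusted p was 0.0364. In 396 genes (98.3%) the libraries of the groups did not overlap, where chance gives 10% for 3 against 3 libraries, although these genes had been selected for their difference. When libraries were rescaled to the median ratio over these 403 genes, 61 were called higher and 150 lower, because that scaling removes the median change of the selected genes themselves. It moved log2 fold changes by -0.88. Changes are given on the authors' scaling throughout.

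**Figure D1:**
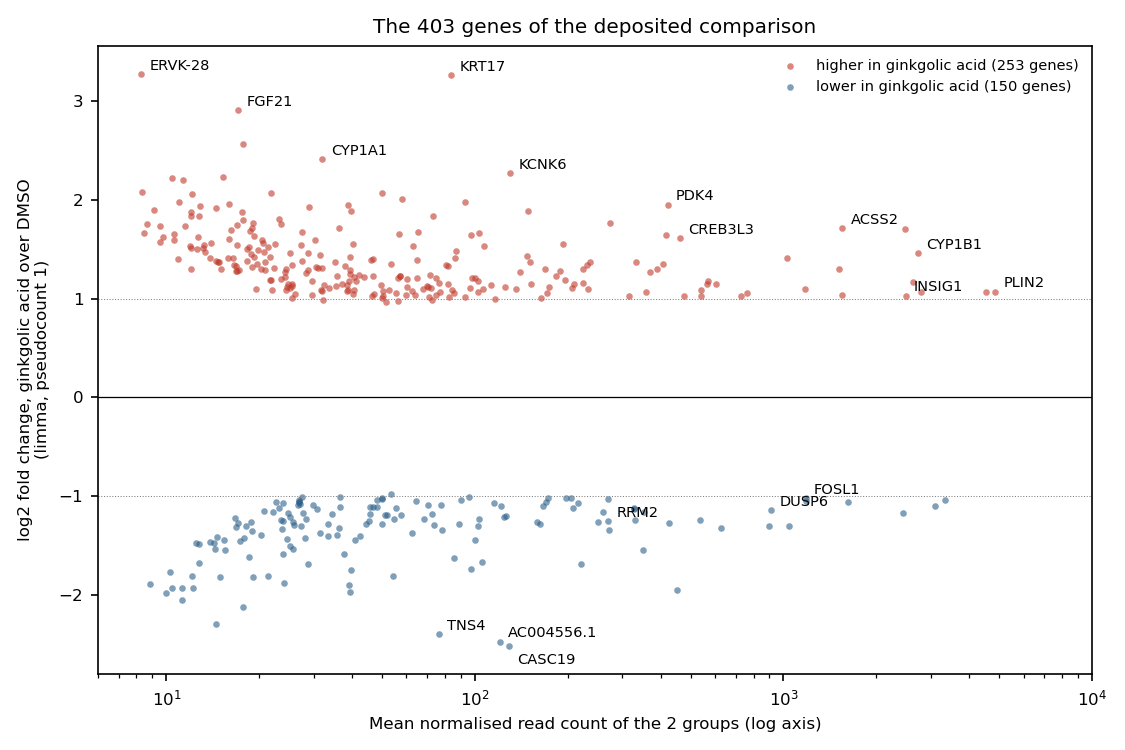
Each point is 1 of the 403 genes, with the mean normalised read count of the groups on a log x axis and the limma log2 fold change of ginkgolic acid over DMSO on the y axis, red for the 253 higher genes and blue for the 150 lower genes. Dotted lines mark a log2 fold change of 1 and -1, and the largest changes, such as those of ERVK-28, KRT17 and CASC19, lie at mean counts well below those of PLIN2, ACSS2 and CYP1B1.

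The 8 largest rises included those of a keratin, a secreted hormone, a cytochrome P450 and a potassium channel. KRT17, which encodes the intermediate filament protein keratin 17 (chromosome 17, 41619441 to 41624842, minus strand), rose from 15.6 ± 6.28 to 152.0 ± 11.8 normalised read counts (SD, n = 3 each), a log2 fold change of 3.26 (SE 0.25, limma adjusted p = 1.29e-07). FGF21, a hormone released by the liver under metabolic stress (chromosome 19, 48755559 to 48758333), rose from 3.60 ± 2.50 to 30.5 ± 9.27. CYP1A1, a monooxygenase induced through the aryl hydrocarbon receptor (chromosome 15, 74719542 to 74725610), rose from 9.87 ± 4.43 to 54.2 ± 4.01. KCNK6, a two-pore-domain potassium channel, rose 4.87-fold, from 44.4 ± 7.59 to 216.2 ± 8.45. LRRC32, which docks latent TGF-beta at the cell surface, rose 6.77-fold, from 4.56 ± 1.90 to 30.8 ± 4.33. The endogenous retroviral transcript ERVK-28 had a log2 fold change of 3.27 (SE 0.67), which rested on 46 reads with ginkgolic acid against 4 DMSO reads, all from DMSO replicate 2. Without that library its log2 fold change was 4.02 and no ratio of reads can be formed, and with pseudocounts of 0.1 and 0.01 in place of 1 it was 5.50 and 7.72, so its size is not settled. Reads of such repeated elements may be split between copies. C11orf42 and AC013394.1 completed the 8 largest rises, with log2 fold changes of 2.23 (SE 0.57) and 2.22 (SE 0.43). Without DMSO replicate 3 that of C11orf42 was 1.54, below that of PDK4 (1.94), so its rank is not settled. AC013394.1 overlaps CHD2 on the same strand, so its reads are uncertain.

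The largest falls included long non-coding transcripts and a protein of focal adhesions. They were ranked by the limma log2 fold change among genes whose libraries did not overlap between the groups. The authors' log2 fold changes rank them differently: AC131392.1 (-2.53), IKBKGP1 (-2.22) and ERICD (-2.21) fell more there than SLC9A4 (-1.92). Further genes, such as AC147067.2 (-2.20) and CPLX2 (-1.96), did so too. CASC19, a long non-coding transcript (chromosome 8, 127072694 to 127227541, minus strand), fell 5.82-fold, from 219.8 ± 26.5 to 37.8 ± 5.01 normalised read counts, a log2 fold change of -2.51 (SE 0.17, limma adjusted p = 5.09e-08). AC004556.1, a protein-coding gene on the scaffold KI270721.1 (2585 to 11802), fell from 203.4 ± 6.47 to 37.2 ± 11.1. TNS4, a tensin, fell from 127.1 ± 7.31 to 25.6 ± 13.4. LINC00973 fell from 24.6 ± 1.92 to 4.45 ± 1.87. The annexin ANXA13 fell 4.88-fold and the sodium-proton exchanger SLC9A4 3.82-fold. A2M-AS1 had a log2 fold change of -1.98 (SE 0.56), which ran from -2.57 without ginkgolic acid replicate 2 to -1.39 without ginkgolic acid replicate 3. A2M-AS1 lies opposite A2M, and without a stated strand setting their reads cannot be separated. CASC19 also overlaps the annotated transcripts PCAT1, PRNCR1 and AC020688.1. Of the 33 named genes 15 overlap another annotated gene on either strand. For ERVK-28, AC013394.1, CASC19, LINC00973, CYP1B1, CYP2E1, NDUFV2 and RRM2 an overlapping gene lies on the same strand, so some of their reads may belong to it. Like A2M-AS1, the genes ACSS2, DDIT4, TP53I3, DUSP6 and LRRC32 overlap a gene on the other strand. Without a stated strand setting some of their reads may belong to that gene too.

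Of the 26 genes in the list of fatty acid oxidation and PPAR target genes, 4 were among the 403 and all 4 rose. PDK4, which blocks pyruvate entry into the citric acid cycle by inactivating pyruvate dehydrogenase, rose 3.89-fold, from 172.5 ± 27.2 to 670.4 ± 88.6 normalised read counts (limma adjusted p = 6.49e-08). CREB3L3, a membrane-bound transcription factor of the liver, rose 3.06-fold, and PLIN2, a coat protein of lipid droplets, rose 2.09-fold, from 3135.9 ± 268.5 to 6567.8 ± 369.9. Drawing 4 genes at random from a table in which 253 of 403 are higher gives 4 higher genes with an exact one-sided p = 0.154, the lowest that 4 genes can give, so the direction of so few genes cannot be told from that of the table. Of the fatty acid synthesis list 1 of 22 genes was selected: ACSS2, the cytosolic enzyme that makes acetyl-CoA from acetate (chromosome 20, 34872146 to 34927962), which rose 3.28-fold, from 724.6 ± 32.0 to 2373.2 ± 33.7 (limma adjusted p = 9.57e-10). Of the cholesterol list 1 of 25 was selected: INSIG1, which holds the SREBP precursors in the endoplasmic reticulum, rose 2.05-fold.

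Both selected members of the 19-gene xenobiotic list, CYP1A1 and CYP1B1, rose. CYP1B1, a monooxygenase induced through the aryl hydrocarbon receptor (chromosome 2, 38066973 to 38109902, minus strand), rose 2.75-fold, from 1449.9 ± 91.1 to 3992.5 ± 196.4 normalised read counts (log2 fold change 1.46, SE 0.07, limma adjusted p = 2.74e-09). The annotated genes RMDN2, RMDN2-AS1 and CYP1B1-AS1 overlap it. Both selected members of the 34-gene ATF4 and integrated stress response list rose: FGF21, and DDIT4, an inhibitor of mTORC1, which went from 2904.4 ± 298.1 to 6139.4 ± 988.3.

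Of the 38 cell cycle genes 2 were selected and both fell: RRM2, the small subunit of ribonucleotide reductase, fell 2.37-fold, from 380.0 ± 35.0 to 160.1 ± 26.2 (limma adjusted p = 5.07e-06), and CDC45, a component of the replicative helicase, fell 2.04-fold, from 263.9 ± 18.3 to 129.4 ± 13.4. Of the 21 immediate early genes 2 were selected and both fell: DUSP6, a phosphatase of ERK that is itself induced by ERK, fell 2.19-fold, from 1256.3 ± 52.8 to 573.1 ± 75.1, and FOSL1, a subunit of AP-1, fell 2.04-fold, from 1584.1 ± 81.0 to 778.2 ± 23.9. NR4A3, a relative of the immediate early list members NR4A1 and NR4A2, is outside that list and was picked out after its value was seen. It was higher, with a log2 fold change of 1.51 in the authors' deposited table. TP53I3, a quinone oxidoreductase and the selected member of the 24-gene p53 list, fell 2.13-fold.

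The remaining lists gave isolated members. Of the 31 hepatocyte genes, ALB (albumin) fell from 19.1 ± 5.97 to 5.30 ± 3.83 and CYP2E1 rose from 9.48 ± 1.77 to 24.3 ± 0.350, both at low counts. The log2 fold change of ALB went from -1.93 to -1.20 without ginkgolic acid replicate 3. NDUFV2, a subunit of respiratory complex I and 1 of 31 genes in the oxidative phosphorylation list, rose 2.27-fold, and 3 annotated genes overlap it. Of the 28 genes in the mesenchymal transition and matrix list 1 was selected, and it was higher. Over all lists 19 distinct genes of the 639 matched symbols were selected, 13 higher and 6 lower. The 403 genes as a whole are out of 16104 that the authors' adjusted p-values imply were tested. These shares were not compared by a test. Each list gene also passed when adjusted over its list alone, which is not independent evidence for genes selected on these libraries. Besides the 3 lists already named, 0 genes were selected from the lists for macroautophagy and lysosome, cytosolic heat shock response, NRF2 targets, the endoplasmic reticulum unfolded protein response, the SUMO pathway, and glycolysis and hypoxia. The same held for mitochondrially encoded messenger RNAs, NF-kappa-B and inflammatory genes, interferon-stimulated genes, metallothioneins, ribosomal proteins and replication-dependent histones. The lists do not cover every gene of a family. HIST2H4A, a histone gene outside the histone list, was picked out after its value was seen. That list has 25 symbols and gives some genes under both an older and a current symbol. HIST2H4A was in the table with a log2 fold change of 1.30 (SE 0.56), and its libraries overlapped between the groups. No gene was selected either from the markers of fibroblasts, leukocytes and endothelium, the other cell types looked for.

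**Figure D2:**
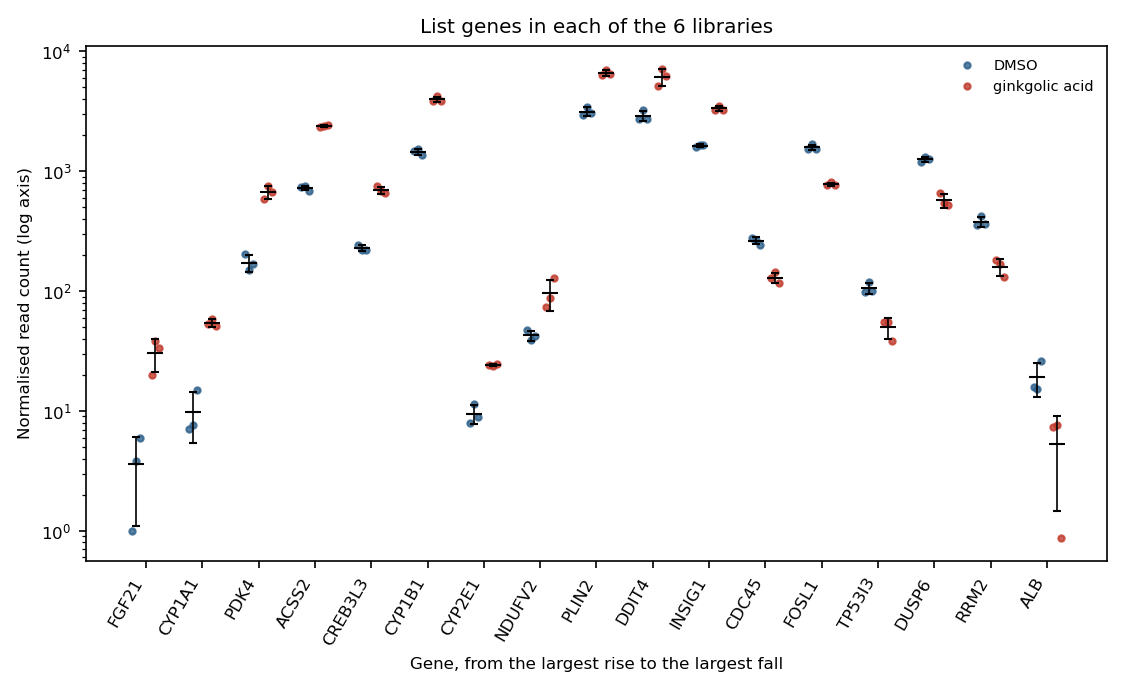
Normalised read counts (log y axis) of 17 list genes, ordered from the largest rise to the largest fall on the log2 scale, with blue points for the 3 DMSO libraries, red points for the 3 ginkgolic acid libraries, and black bars for the mean and SD of each group. For every gene drawn the libraries of the groups do not overlap, and FGF21, CYP1A1, CYP2E1 and ALB lie at the lowest counts.

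Counts were low for much of the table. The median gene had a mean of 39.5 normalised read counts and 230 genes had a mean under 50. Of the 19 genes with a mean of at least 1000, 12 were higher and 7 lower. By biotype, 268 genes were protein-coding (171 higher, 97 lower), 40 were lincRNAs (19 higher, 21 lower) and 34 were antisense transcripts (22 higher, 12 lower). In Fisher's exact tests of each biotype against all other genes, the smallest two-sided p was that of lincRNAs (p = 0.0396), which leaned lower than the rest, followed by sense-intronic transcripts, of which 10 of 11 were higher (p = 0.0599). Both had an adjusted p = 0.359 over 12 biotypes, so no biotype differed in direction beyond chance after adjustment.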

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

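The alternatives were chosen before the data were examined. The counts of 253 higher and 150 lower genes, and of 13 higher and 6 lower list genes, stayed within 1.5 times under every alternative but one. Median-of-ratios rescaling over the genes held gave 61 higher genes and 7 higher list genes. By its construction it centres the libraries on changed genes, and INSIG1, PLIN2, DDIT4, NDUFV2 and CYP2E1 were among the named genes no longer past the threshold under it. No named gene changed direction under any alternative. All genes had been selected on these same libraries, so stable counts were largely fixed in advance and are not independent evidence. Leaving out each library in turn gave 250 to 253 higher and 148 to 150 lower genes, and 13 higher and 6 lower list genes each time. All named genes stayed past the threshold, but the size of low-count changes moved: log2 fold changes ran from -2.57 to -1.39 for A2M-AS1, 2.89 to 4.02 for ERVK-28, 1.54 to 2.64 for C11orf42, -2.30 to -1.20 for ALB and 2.39 to 3.30 for FGF21. KRT17 lay above ERVK-28 without DMSO replicate 1 or 3 (3.12 against 2.89 each) and without ginkgolic acid replicate 3 (3.33 against 3.25). Smaller pseudocounts raised the log2 fold change of ERVK-28 to 5.50 (pseudocount 0.1) and 7.72 (pseudocount 0.01, limma adjusted p = 0.048). Deviations of same-numbered libraries from their group means correlated at -0.03, 0.00 and -0.07 across genes. Every gene had the same weight there, and the median gene had a mean of only 39.5 normalised read counts. Counting noise can hide a shared replicate effect in such a correlation, so pairing of the libraries by replicate number is not excluded. With the replicate number as a block the counts were again 253 and 150, with 13 and 6 list genes. The limma adjusted p fell with the block for every named gene but CYP2E1, and for PLIN2 it went from 3.4e-08 to 4.1e-18. That of CYP2E1 rose from 0.0013 to 0.0024. With no block, the limma adjusted p of PLIN2 also moved when a library was left out. It was 3.3e-12 without ginkgolic acid replicate 2 and 4.4e-07 without ginkgolic acid replicate 3. A lower p with the block therefore does not show that the libraries were paired. The filters removed 0 genes, so they tested nothing. At an adjusted p under 0.01 in the authors' deposited table, 188 genes were higher and 106 lower. Rescaling to TPM and list tests with camera or fry were not run, since the table holds selected genes only. A count model on recovered reads had been planned as an added alternative and was not run either. In the simulation 2-fold changes were called in 83.6% of genes, and low counts limit the size of folds such as that of ERVK-28.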

Other observations

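The genes of this paragraph and the next were chosen after their values were seen, and all passed the limma test at an adjusted p under 0.05. TXNIP, which binds and inhibits thioredoxin, had the smallest p-value in the authors' deposited table and rose 3.26-fold, from 1163.5 ± 56.5 to 3791.6 ± 109.7 normalised read counts (SD, n = 3 each). Its arrestin-domain relative ARRDC4 rose 3.12-fold. Genes of lipid biology went both ways, and they were not tested as a group. Higher were the droplet proteins PLIN1 (2.29-fold), PLIN5 (2.70-fold) and CIDEC (2.08-fold, from 496.3 ± 47.6 to 1032.2 ± 93.3), hormone-sensitive lipase LIPE (4.03-fold), the fatty acid carrier FABP3 (4.06-fold) and the glycerol channel AQP7 (2.40-fold), and lower were the peroxisomal oxidase ACOX2 (2.40-fold) and the lipid transporter ABCA12 (2.18-fold). SEC24A and SEC24D, cargo adaptors of COPII vesicles, rose 2.06-fold and 2.46-fold. PGM3 and GFPT2, enzymes of UDP-N-acetylglucosamine synthesis, rose 2.15-fold and 2.45-fold. LAMB3, the laminin beta-3 chain, rose 2.26-fold.

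Among the lower genes, the GINS helicase subunits GINS2 (2.14-fold) and GINS4 (2.03-fold), the checkpoint adaptor CLSPN (2.02-fold) and the kinetochore protein SPC25 (2.33-fold) fell beside CDC45 and RRM2. ODC1, the first enzyme of polyamine synthesis, fell 2.47-fold, from 1280.7 ± 86.4 to 518.5 ± 10.8, and the nucleoside diphosphate kinase NME1 fell 2.50-fold. HNRNPM, a splicing regulator and an abundant transcript, fell 2.05-fold, from 4507.6 ± 189.0 to 2194.6 ± 127.2. The collagenase MMP1 fell 2.46-fold and the kynurenine pathway enzyme KYNU 2.24-fold. The epidermal barrier genes FLG and HRNR, neighbours on chromosome 1, fell 2.49-fold and 2.62-fold. FLG-AS1, which was lower as well, overlaps both on the other strand. Without a stated strand setting its reads cannot be separated from theirs.

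The adjusted p-values of the authors' deposited table hold information on genes outside it. For the gene with the smallest p-value, adjusted p divided by p gives 16104, the number of genes tested if that gene ranked first. With that number, the last gene of the table has rank 5316 by p-value. The 403 genes would then be 7.6% of those with an adjusted p at or under that of the last gene, and they take 25 of the first 100 ranks. Responses of under 2-fold therefore lie outside the comparisons reported here.

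Genes that lie close together tended to change in the same direction, a pattern noticed in these data and tested on them. Of 10 overlapping pairs 9 shared a direction (90.0%, against a median of 50% when directions were shuffled 10000 times, one-sided permutation p = 0.019, adjusted p = 0.032 over 5 tests). Of the 22 pairs within 100 kb that do not overlap, 77.3% also shared a direction (one-sided permutation p = 0.019, adjusted p = 0.032). The upper 95% limit of shuffled directions was 72.7%. Some of these pairs are linked by another gene of the table. FLG-AS1 overlaps both HRNR and FLG, and BCAN overlaps both AL365181.3 and AL590666.2. The 22 pairs therefore cannot decide whether reads counted for an overlapping gene are the cause. A test chosen after this result was seen kept the pairs in which neither gene overlapped another gene of the table. Of these 15 pairs, 13 shared a direction (86.7%, one-sided permutation p = 0.0059, adjusted p = 0.029). That choice left out the pairs of HAPLN2 with BCAN, AL365181.3 and AL590666.2, which differed in direction, as well as pairs that shared one. Reads shared by overlapping genes of the table are argued against for these 15 pairs only. Overlap with genes outside the table was not screened, so reads counted for such genes stay open. Among the 103 pairs 100 kb to 1 Mb apart 60.2% shared a direction, inside the shuffled range (upper 95% limit 63.1%, one-sided permutation p = 0.099, adjusted p = 0.099). Near-identical copies that share reads stay open. Without pairs sharing a symbol root the share was 72.2% of 18 pairs, inside the shuffled range (upper 95% limit 77.8%, one-sided permutation p = 0.086, adjusted p = 0.099). Such a root does not mark near-identical copies, so this does not test them. Transcription running past gene ends and shared local regulation were not tested.

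More genes of the table were higher than lower. The excess was not confined to the genes with the lowest counts. Among the 202 genes at or above the median mean count 61.9% were higher, with a lower exact 95% bound of 54.8%, against 63.7% of the 201 others. That bound treats genes as independent, and the median mean count was only 39.5, so counting noise is not excluded as a cause. A scaling error between the groups and an effect of the treatment cannot be told apart here. A shift of all log2 fold changes by 0.26 would equalise the counts if no gene entered the table, and the genes that would enter it were not analysed here.

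The 3 ginkgolic acid and 3 DMSO libraries form 10 splits into groups of 3, too few for a share under 0.05. The real split called 403 genes and the highest other split 0, and 1 of the 10 splits gave as many genes. The genes had been selected on the real split.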
